A study of Mus musculus with 6 samples.

How the data were processed

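RNA from 6 tumours was measured on Affymetrix expression arrays, with 1 array per tumour. The tumours grew from 4T1 cells, a mouse mammary tumour line: 3 from control cells and 3 from cells in which Bptf had been knocked down (KD). Per the labels' protocols, short hairpin RNAs against Bptf were delivered with a retrovirus, 10000 cells were placed in the fourth mammary fat pad of NSG mice, and the tumours were collected on day 21. NSG mice lack mature T, B and natural killer cells. The tissue was stained with hematoxylin and eosin, necrotic areas were dissected away where there were any, and 500 ng of total RNA per tumour went into biotin-labelled cRNA, per the labels' protocols. What the control cells carried, which part of Bptf the hairpins target and the shares of tumour and stromal cells in each piece are not given in the sources used here.

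The deposited values are log2 expression values made with RMA (background correction, quantile normalisation and summary of the probes of each probe set), per the submitters' processing notes, which give no version. The base of the logarithm is not given in the sources used here. It was taken as 2, RMA's own scale, because the values ran from 2.98 to 15.17. They are rounded to 2 decimals, 1 column per tumour, and no column pools tumours. The deposited table holds 22690 probe sets, of which 64 are the manufacturer's controls. GEO's platform annotation gave 1 gene for 20380 probe sets and several for 691, and 1555 were unnamed here. Symbols were matched by Entrez identifier to a RefSeq gene table of the assembly GRCm38.p6, used only for names. No symbol changed, and 29 probe sets without a match kept the name of the annotation. No coordinates are given, since no genome build is named for the values.

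Of the 12393 genes with a probe set of their own, 4956 had several. The probe set with the highest mean over the 6 arrays stood for the gene, and probe sets whose mean lay in the lowest 30% of all (below a log2 value of 6.09) were left out. This left 9248 genes. RMA values carry no detection call, so how much of a dim level is background is not known. No values were normalised again for the main results.

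Bptf KD was compared with control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 groups, no covariate), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. All adjusted p-values of genes come from this limma fit unless another is named. Differences are log2 Bptf KD minus control. Single values were also compared with an exact two-sided permutation test of the means, which cannot go below p = 0.1 with 3 tumours in each group. The tumours are separate biological samples per the labels. Whether each came from its own mouse is not given in the sources used here. The number of arrays limits the precision.

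Of 28 gene lists, 27 were tested with camera, from limma, at a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Lists needed 3 measured genes, which left out the red blood cell list, with 1 of 10 genes measured. Each list was also tested by camera with the correlation estimated from the arrays, and by fry, whose main p asks whether the genes of a list move, on balance, in one direction and whose mixed p asks whether they change in either direction. RNA quality was read as the log2 difference between the 3-prime and 5-prime control probe sets of Actb and Gapdh.

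The grouping, the tests of the comparison, the lists, the rule for the genes to be named and the alternatives were fixed before the data were examined, except for the added alternative with the mean of the skeletal muscle list as a covariate. Several tests of technical explanations were also chosen later, and are named as such in the closing section. The rule for the genes to be named takes Bptf and the measured members of the list of NURF and related complexes. It takes the 10 genes with the largest differences in each direction among those past the threshold. It takes up to 4 members with the smallest p of each list described, and Psmb8, Psmb9, Psmb10, Tap1, Tap2, Tapbp, B2m, H2-K1 and H2-D1 of the MHC class I list. Genes named outside this rule were chosen after their values were seen, and are named as such.

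The alternatives were no filter and a stricter filter (lowest 50%) on dim probe sets, the mean of all probe sets of a gene or the one with the largest SD, median centring, a second quantile normalisation, eBayes with trend and robust settings, array weights, the replicate number as a block, an ordinary test without moderated variance, an added fold threshold, an estimated correlation for the lists, and leaving out each tumour in turn. The procedure was tested on simulated data of 9248 genes in 3 arrays against 3, with 200 genes changed, over 20 runs. It recovered 73.8% of genes changed by 1 log2 unit and 97.8% of those changed by 2, and 4.49% of its calls were false. A list shifted by 0.35 was called in 20 of 20 runs, with 0.15 calls of other lists per run. The simulated genes were independent of each other and no array stood apart. These rates therefore do not carry over to the real lists, whose estimated correlation was 0.201 for interferon and 0.456 for the cell cycle. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.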

Results

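Gene expression was measured in 3 control and 3 Bptf KD 4T1 tumours, each on an array of its own. Bptf is the largest subunit of NURF, a chromatin remodelling complex, and the series is concerned with whether tumours depleted of NURF are more visible to CD8 T cells. The mice that carried these tumours lack such cells. Median log2 values lay between 7.60 and 7.70 on all 6 arrays. Across genes, which are not independent replicates, the Bptf KD tumours correlated with each other at 0.984 to 0.988 and controls 1 and 3 at 0.986, while the tumour labelled control 2 correlated with the other controls at 0.934 to 0.939. In that tumour 8.66% of genes lay at least 2-fold from the mean of the other 2 controls, against 0.443% to 2.51% for each of the other 5 tumours.

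Bptf itself, the target of the hairpins, was read first, because it checks the labels. Its brightest probe set gave log2 levels of 10.69, 9.77 and 10.59 in controls 1, 2 and 3, and of 9.60, 9.56 and 9.99 in the 3 Bptf KD tumours. The means were 10.35 ± 0.50 and 9.72 ± 0.24 (SD, n = 3 each), so that the Bptf KD level was 0.645 times that of the controls. The difference of -0.63 (SE 0.27) did not pass the threshold (limma adjusted p = 0.371) and had an exact two-sided permutation p of 0.2. The target went against the label in control 2. On the other 3 probe sets that tumour lay below every Bptf KD tumour: at 7.59 against 8.37 to 9.15 on 1 of them, at 5.41 against 6.37 to 6.53 on another and at 6.88 against 7.27 to 7.37 on the last. It is therefore called the tumour labelled control 2, and every direction given for Bptf KD against control counts it among the controls. Across 33 genes with long transcripts, the median difference from controls 1 and 3 was -0.76 in the tumour labelled control 2 and -0.39 in the Bptf KD tumours. Without that control, Bptf was lower in Bptf KD tumours by a difference of -0.92, past the threshold (limma adjusted p = 0.0305; range over all alternatives 0.00905 to 0.730). Leaving out each tumour in turn was planned. This tumour, however, had the lowest Bptf of the controls, so leaving it out favours a smaller p, which is not independent evidence of the knockdown.

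**Figure D1:**
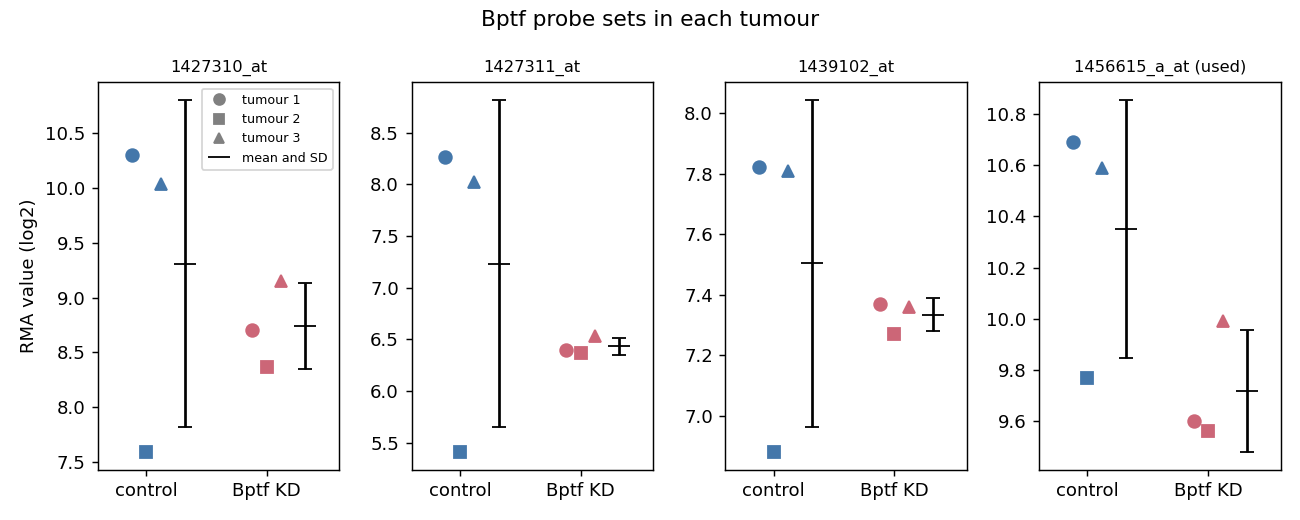
Log2 RMA level of each of the 4 Bptf probe sets in each of the 6 tumours (points), with the mean and SD of each group of 3. The tumour labelled control 2 sits at 9.77 on the probe set used for the gene, within the range of the Bptf KD tumours (9.56 to 9.99), and below all of them on the other 3.

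The other measured subunits of NURF and of related ISWI complexes did not pass the threshold. Smarca5, an ATPase of the ISWI family, differed by -0.05, and the histone-binding subunits Rbbp4 and Rbbp7 by 0.01 and -0.25. Hmgxb4 differed by 0.33, Baz1b by -0.02, Baz2a by 0.11, Chrac1 by 0.28 and Pole3 by -0.10. Of the 9 list members measured, Bptf included, limma called 0, and 0 had an unadjusted p under 0.05. The list had a median difference of -0.02 (camera adjusted p = 0.577). The sign of Baz1b depended on the probe set, and those of the list median, Smarca5, Rbbp4, Baz1b and Baz2a changed in at least 1 alternative.

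The comparison of Bptf KD with control tumours asks which genes differ when 4T1 cells grow with less Bptf. Of 9248 genes, 75 passed the threshold, 61 lower and 14 higher in Bptf KD tumours, and 6 of the lower genes are on the adipocyte list. Of these 64 differed at least 2-fold, and 22 of the lower genes at least 4-fold. Over all genes tested, the groups did not overlap in 1851, a pattern that chance gives in 10% of genes. Car3, a carbonic anhydrase abundant in fat and muscle, fell 12.7-fold, from 13.81 ± 0.30 to 10.14 ± 0.28 (SD, n = 3 each; limma adjusted p = 0.00364). Cidec, a lipid droplet protein, fell from 9.02 ± 0.76 to 5.34 ± 0.38 (adjusted p = 0.0154 from limma), a level below the dim level of 6.09, so the size of its fold and its rank are uncertain. The other 8 of the 10 largest decreases were those of the matrix glycoprotein Efemp1 (-3.58), the fatty acid desaturase Scd1 (-3.52), lipoprotein lipase Lpl (-3.27), the fatty acid transporter Cd36 (-3.15), Apod (-2.87), the fatty acid binding protein Fabp4 (-2.85), the protease inhibitor Serpina3n (-2.80) and the chemokine Cxcl12 (-2.70). Some sizes and ranks depended on the probe set. The smallest fall among probe sets above the dim level was -1.82 for Scd1, -1.31 for Fabp4 and -1.44 for Cxcl12, but -3.14 for Lpl and -2.99 for Cd36.

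Among the genes that rose, Cldn2, a pore-forming claudin of tight junctions, was 4.80-fold higher, at 9.17 ± 0.29 against 6.90 ± 0.25 (SD, n = 3 each; limma adjusted p = 0.00986). Ncmap rose by 2.10, Rerg by 1.45, the peroxisomal oxidase Acox2 by 1.37, Tmem184a by 1.26 and the heparan sulfate sulfotransferase Hs3st1 by 1.24. The actin-binding protein Dmtn rose by 1.03, Marveld3, a protein of tight junctions, by 0.98, Eva1c by 0.93 and the growth factor Pdgfc by 0.88, with adjusted p from 0.0355 to 0.0497 among these 9 genes. At an unadjusted p under 0.05 there were 708 higher and 538 lower genes, where 462.4 in total would be expected by chance, so the larger share of lower genes held among the calls and not at this level. With array weights, too, more genes were called higher (986) than lower (690). The count depended on which tumour was left out. It was 73 without control 1, with 45 of the 75 shared. It was 412 without the tumour labelled control 2 (179 higher, 233 lower), with all of the 75 included, and 10 without control 3, 2 without Bptf KD 1, 6 without Bptf KD 2 and 0 without Bptf KD 3, where limma gave 742 genes at an unadjusted p under 0.05, and the 75 kept their direction in each. The 75 were chosen by their difference in these same tumours, so that their direction held is not independent evidence. With all tumours kept, the stricter filter left 42 genes called and an ordinary test without moderated variance 1. The calls of Ncmap, Hs3st1 and Pdgfc ended with a second quantile normalisation, and those of Rerg, Acox2, Tmem184a, Dmtn, Marveld3, Eva1c, Pdgfc and Cd36 ended with the muscle list as a covariate, with their directions kept. The replicate number as a block ended those of Ncmap, Acox2, Dmtn, Eva1c and Pdgfc, and the stricter filter and the probe set with the largest SD that of Pdgfc.

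Markers of fat cells and of fibroblasts were lower as groups in Bptf KD tumours. All 12 measured adipocyte markers had negative differences, with a median of -2.64. Car3, Fabp4, Retn (-2.62), Lpl, Plin4 and Cidec fell with adjustment over all genes by limma, and 11 fell adjusted over the list alone. Adipoq had the largest difference of the list (-4.65), with an SD of 2.52 among Bptf KD tumours, and did not pass (limma adjusted p = 0.159). The list mean was 9.38 to 10.09 in the controls and 6.95 to 7.72 in the Bptf KD tumours. All 25 fibroblast and matrix markers were also negative, with a median of -0.77: the collagens Col1a1 (-1.81), Col3a1 (-0.91) and Col6a3 (-1.22), the proteoglycan Dcn (-1.70) and Dpt fell over all genes, and 19 fell adjusted over the list alone. The calls of Dcn and Col3a1 ended with the muscle list as a covariate and that of Col1a1 with the mean of its probe sets. Adipoq, Plin4 and Dpt were chosen after their values were seen. The fibroblast list mean was 11.0 to 11.3 in controls and 10.1 to 10.3 in Bptf KD tumours. By camera the adjusted p was 1.86e-20 for the adipocyte list (adjusted p = 0.182 with an estimated correlation) and 5.82e-20 for the fibroblast list (adjusted p = 0.182 with an estimated correlation). Both passed by fry (adjusted p = 0.0160 and 0.0180). The fat pad into which the cells were injected holds both cell types.

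**Figure D2:**
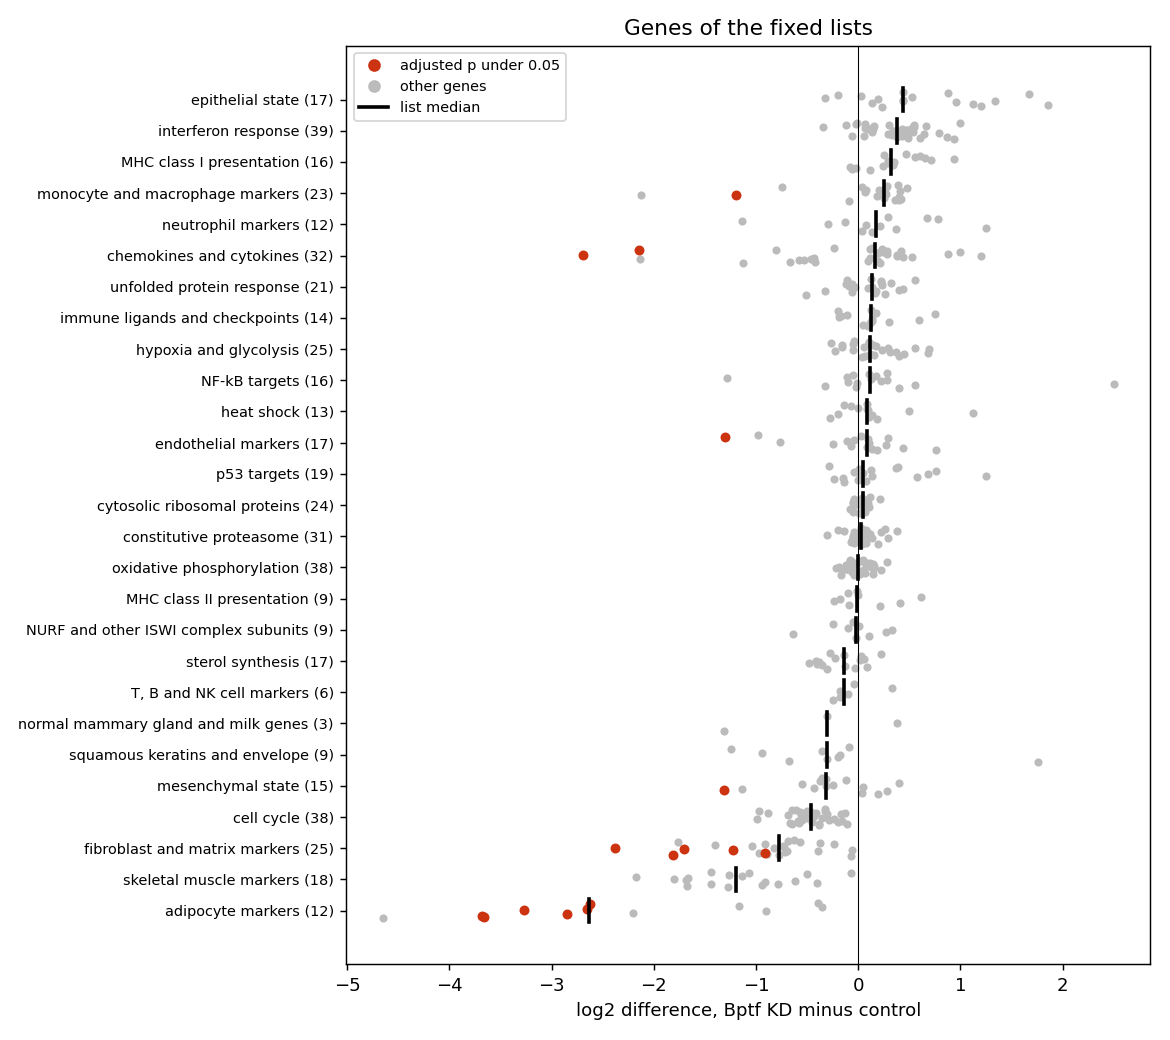
Log2 difference, Bptf KD minus control, of the measured genes (points) of each of the 27 gene lists tested, with the list median as a bar and genes past the adjusted threshold in red. The adipocyte list (-2.64), the muscle list (-1.20) and the fibroblast list (-0.77) lie furthest to the lower side, and the epithelial (0.44), interferon (0.38) and MHC class I (0.32) lists furthest to the higher side.

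**Figure D3:**
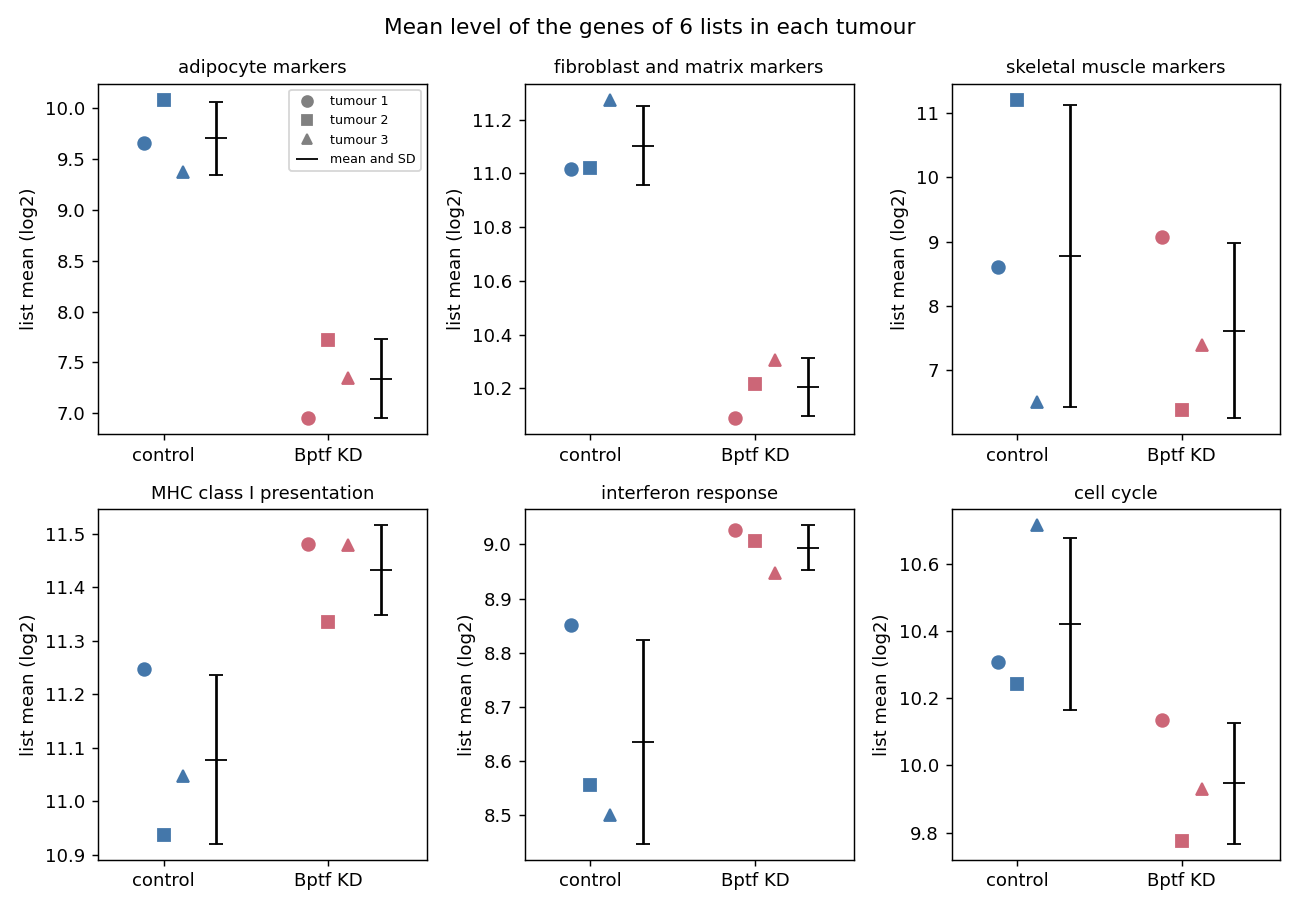
Mean log2 level of 6 gene lists in each of the 6 tumours, by group. Points are list means and bars the mean and SD of each group; the adipocyte list lies at 9.38 or more in the controls and at 7.72 or less in the Bptf KD tumours, while the muscle list is highest in the tumour labelled control 2.

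Genes of MHC class I presentation were the question of the series. As a list they were higher in Bptf KD tumours, and no single member passed over all genes. The 16 measured members had a median difference of 0.32, and 13 were positive. The immunoproteasome subunits Psmb9 and Psmb8 differed by 0.94 and 0.71 (1.91-fold and 1.64-fold), the proteasome activator Psme1 by 0.65, and the peptide transporter subunit Tap1 by 0.56, and these 4 rose adjusted over the list alone. Their adjusted p over all genes ran from 0.0836 to 0.204 in limma, which called 0 of the 16, with 6 higher at an unadjusted p under 0.05. Tap2 differed by 0.60, H2-K1 by 0.34, Psmb10 by 0.29, Tapbp by 0.26, H2-D1 by 0.24 and B2m, the light chain of class I, by 0.11. Sizes depended on the probe set. Those above the dim level gave 0.097 and 0.56 for Tap1 (2 probe sets) and 0.0033 to 0.68 for H2-D1 (8 probe sets). Tapbp was negative without the tumour labelled control 2, with array weights and with the muscle list as a covariate. The list passed by camera (adjusted p = 9.39e-04), but not with an estimated correlation (adjusted p = 0.427 with an estimated correlation) nor without the tumour labelled control 2 (median 0.25, adjusted p = 0.0519; range over all alternatives 1.38e-04 to 0.427). By fry the list did not pass either (adjusted p = 0.146). The tumour labelled control 2 had the highest control levels of Psmb8 (12.42) and Psmb9 (10.38), and leaving it out raised the calls over all genes from 75 to 412. Leaving it out therefore favours a smaller p, which is not independent evidence for these genes. Without that tumour Psmb8 (0.89, adjusted p = 0.0181) and Psmb9 (1.05, adjusted p = 0.0267) passed over all genes in limma. With array weights, for which limma warned that its fit had not converged, these and Tap1, Psme1 and H2-K1 passed (adjusted p from 0.00227 to 0.0334; over all alternatives these 5 genes ranged from 0.00227 to 0.724). Psmb8, Psmb9, Tap1 and Tap2 were put among the fixed genes with published work on Bptf depletion in mind, recalled and not given in the sources used here, so the list is not independent evidence of its direction.

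**Figure D4:**
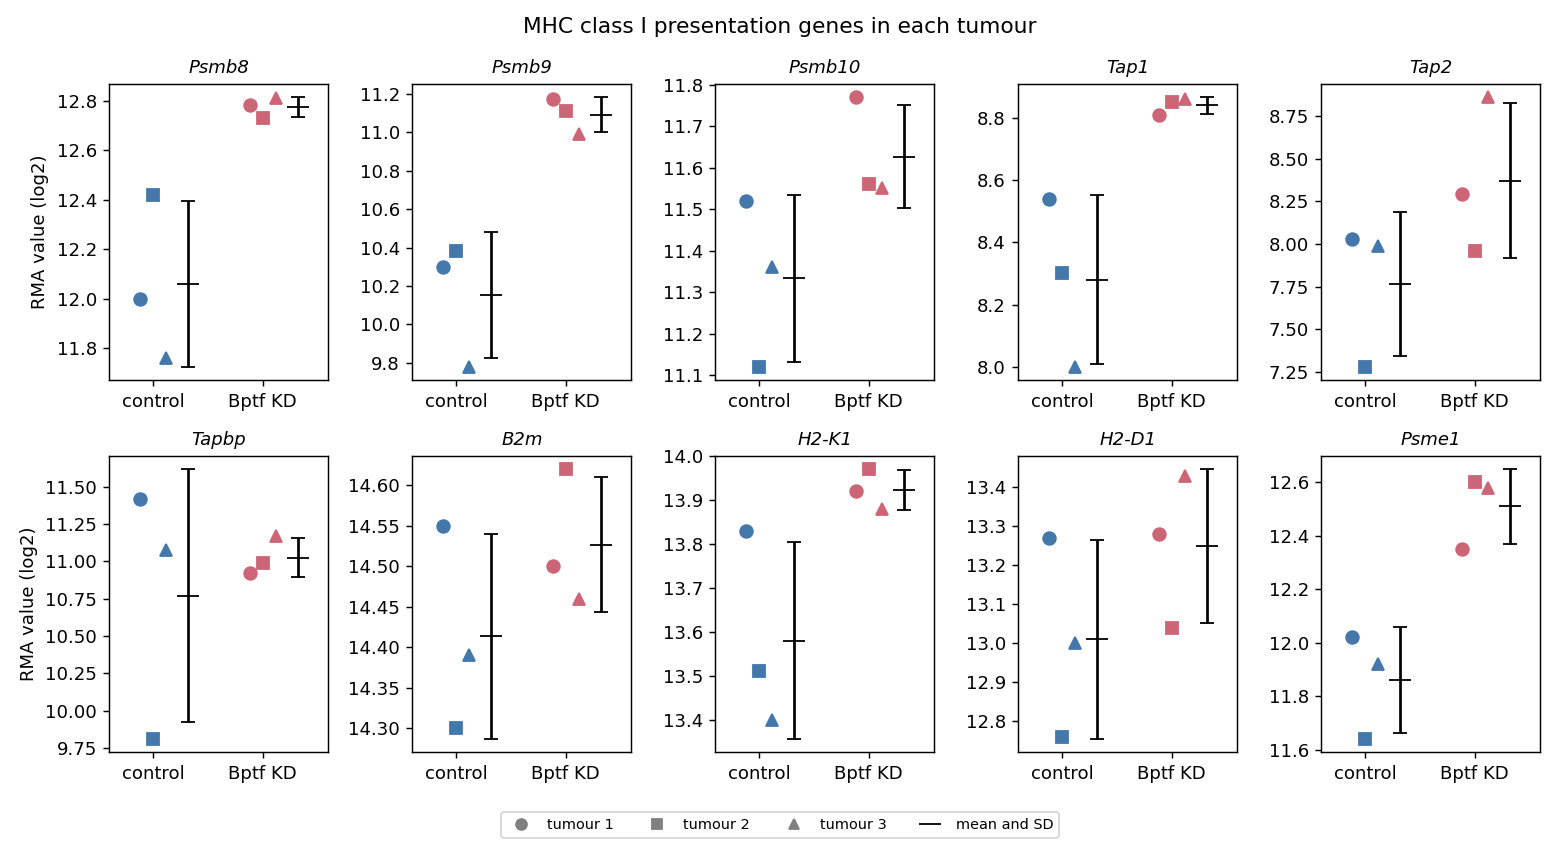
Log2 RMA level of 10 MHC class I presentation genes in each tumour (points), with the mean and SD of each group of 3. Psmb8, Psmb9, Tap1 and Psme1 are higher in every Bptf KD tumour than in every control, while Tapbp, B2m and H2-D1 overlap between the groups.

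Interferon-responsive genes were also higher as a list. The 39 measured genes had a median of 0.38, and 34 were positive. Usp18, which removes the ubiquitin-like protein Isg15 from its targets, was higher by 1.00 on the log2 scale, and Bst2, which tethers budding viruses, by 0.94 (1.91-fold). Both rose adjusted over the list alone. Irf9, a transcription factor of the type I interferon response, differed by 0.48 and Rtp4 by 0.55. Limma called 0 of the 39 over all genes, with 10 higher and 1 lower at an unadjusted p under 0.05. The tumour labelled control 2 had the highest control levels of Usp18 (8.35, beside 8.34 and 7.92) and Bst2 (8.53, beside 8.37 and 8.35). Leaving it out therefore favours a smaller p, which is not independent evidence for these genes. Without the tumour labelled control 2, Usp18 (1.07, limma adjusted p = 0.0248; range over all alternatives 0.00219 to 0.238) and Bst2 (0.99, limma adjusted p = 0.0438; range 0.00648 to 0.293) passed over all genes, and Usp18 also passed with the replicate number as a block. Both, Irf9 and Rtp4 passed with array weights. The list passed by camera (adjusted p = 1.03e-05; adjusted p = 0.427 with an estimated correlation). By fry the interferon list did not pass (adjusted p = 0.146). The list mean was 8.50 to 8.85 in controls and 8.95 to 9.03 in Bptf KD tumours. MHC class II presentation did not pass: its 9 genes had a median of -0.01 and a mean of 0.07, of opposite sign (camera, direction down, adjusted p = 0.961), with Ctss at 0.41 and H2-Aa at -0.24. The 31 constitutive proteasome subunits had a median of 0.02 (camera adjusted p = 0.991), and the 14 immune ligands and checkpoints of 0.12 (camera adjusted p = 0.577), with Cd86 at 0.60 and Lgals9 at 0.75.

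Genes of the epithelial state were higher and genes of the mesenchymal state and the cell cycle lower as lists. Of 17 epithelial genes 15 were positive, with a median of 0.44. The tight junction genes Cldn4 (1.86), Ocln (1.67) and Cldn3 (1.20) rose adjusted over the list alone, while Jup, a junction protein, differed by 0.44. Limma called 0 of the 17 over all genes, and 9 were higher at an unadjusted p under 0.05. Cldn3 passed with the replicate number as a block (limma adjusted p = 0.0281; range over all alternatives 0.0281 to 0.456), Cldn4 without control 1 (limma adjusted p = 0.0381; range 0.0238 to 0.336), and Cldn4, Ocln and Jup with array weights. Of 15 mesenchymal genes 10 were negative, with a median of -0.31. The matrix metalloproteinase Mmp2 fell over all genes (-1.31, limma adjusted p = 0.0392; the call ended with the muscle list as a covariate), and Tnc (-0.55), S100a4 (-0.43) and Mmp9 (-1.13) did not pass. The fibroblast and matrix markers moved with this list (median -0.77, all 25 negative). All 38 cell cycle genes were negative, with a median of -0.46, among them the replication licensing genes Mcm5 (-0.56) and Mcm2 (-0.46) and the mitotic genes Cdc20 (-0.59) and Cenpe (-0.99). Limma called 0 of them over all genes, and 17 were lower at an unadjusted p under 0.05, while 4 were called lower without the tumour labelled control 2 (Cdc20, Foxm1, Mki67 and Rrm2, the last 3 chosen after their values were seen). Leaving that tumour out raised the calls over all genes from 75 to 412. Tnc, S100a4, Mmp9, Mcm5, Mcm2, Cdc20 and Cenpe passed with array weights. Camera gave adjusted p = 9.39e-04 for the epithelial list (adjusted p = 0.427 with an estimated correlation), 0.00261 for the mesenchymal list (adjusted p = 0.393 with an estimated correlation) and 1.77e-15 for the cell cycle list (adjusted p = 0.427 with an estimated correlation). None of these lists passed by fry (adjusted p = 0.146 for the epithelial list, 0.154 for the mesenchymal list and 0.154 for the cell cycle list). With array weights the epithelial list missed the threshold (camera adjusted p = 0.0727; range over all alternatives 4.87e-06 to 0.427).

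Skeletal muscle genes set the tumour labelled control 2 apart. Its muscle list mean was 11.2, against 8.61 and 6.51 in controls 1 and 3 and 6.39 to 9.08 in the Bptf KD tumours, and all 18 measured muscle genes lay at least 2-fold above the mean of controls 1 and 3. Ckm, muscle creatine kinase, was 5.35 higher there. Keratinocyte genes were higher too: the list of squamous keratins and envelope genes by a median of 1.53, with Krt14, a basal keratin, at 3.49 and Lor, a protein of the cornified envelope, at 3.63. Neutrophil markers were higher by a median of 0.70, and the hypoxia and glycolysis list differed by a median of -0.62. Ckm, Krt14 and Lor were chosen after their values were seen. Between the groups the muscle list was lower in Bptf KD tumours (median -1.20, camera adjusted p = 0.00261; adjusted p = 0.863 with an estimated correlation), with all 18 genes negative, among them Pvalb (-2.17) and Tnnt3 (-1.44), 0 called by limma and 0 at an unadjusted p under 0.05. Without the tumour labelled control 2 the muscle median was 0.02 (camera adjusted p = 0.901), and without Bptf KD 2 it was -0.57 (camera adjusted p = 0.108; range over all alternatives 2.77e-10 to 0.901), and array weights turned it to 0.88. With all tumours the muscle list did not pass by fry (adjusted p = 0.692). Without the tumour labelled control 2 the adipocyte median was -2.45 and the fibroblast median -0.89.

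RNA quality did not differ between the groups beyond the spread of the tumours for Actb and Gapdh. The 3-prime minus 5-prime difference of Actb averaged 0.92 ± 0.27 in controls and 0.91 ± 0.15 in Bptf KD tumours (SD, n = 3 each; exact two-sided permutation p = 0.9), and that of Gapdh -0.027 ± 0.076 and -0.013 ± 0.046 (exact p = 0.8). The highest Actb value, 1.23, was that of the tumour labelled control 2. For the control probe sets of Pcx, the difference was 0.27 to 0.72 in the controls and -0.29 to -0.08 in the Bptf KD tumours, without overlap, and for Tfrc it was 1.34 to 1.54 over all tumours.

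Lists of other cells that the pieces hold did not pass as a whole with all tumours and the main settings. Of 23 monocyte and macrophage markers 19 were positive, with a median of 0.26 (camera adjusted p = 0.375), although Cd209a fell (-1.20, limma adjusted p = 0.00986). The 17 endothelial markers had a median of 0.09, a mean of -0.07 and a camera direction of down (adjusted p = 0.408), and Tek, the angiopoietin receptor, fell by 1.30 (limma adjusted p = 0.00986). The 12 neutrophil markers had a median of 0.17 (camera adjusted p = 0.577) and passed without the tumour labelled control 2 (median 0.37, camera adjusted p = 0.0298; adjusted p = 0.472 with an estimated correlation; range over all alternatives 0.0298 to 0.974). The 6 measured T, B and NK cell markers, from cells these mice lack, had a median of -0.14 (camera adjusted p = 0.219), and the 3 measured genes of normal mammary gland and milk -0.30 (camera adjusted p = 0.113), with the casein gene Csn3 at -1.32. That list passed without the filter on dim probe sets (median -0.61, camera adjusted p = 1.61e-05) and without control 3 (-0.38, camera adjusted p = 0.0239; range over all alternatives 1.61e-05 to 0.427), and had an adjusted p = 0.427 with an estimated correlation and all tumours. The 9 squamous genes had a median of -0.30 (camera adjusted p = 0.249), with the desmosomal gene Dsc2 at 1.76, which rose adjusted over the list alone from a dim control level of 5.59. The squamous list passed without the filter (camera adjusted p = 0.0237) and without control 1 (median -0.51, camera adjusted p = 0.0275; range over all alternatives 0.0237 to 0.984), and its median was 0.06 without the tumour labelled control 2. With all tumours it had an adjusted p = 0.863 with an estimated correlation.

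Signalling, stress and metabolic lists did not pass either with the main settings. Chemokines and cytokines had a median of 0.16 over 32 genes but a mean of -0.15 and a camera direction of down (adjusted p = 0.408), and passed with the stricter filter (camera adjusted p = 0.0204; range over all alternatives 0.0204 to 0.793; adjusted p = 0.793 with an estimated correlation and the main filter). Il33, an alarmin, fell by 2.14 (limma adjusted p = 0.00986), as did Cxcl12, and adjusted over the list alone 5 genes fell and 2 rose, among them Ccl8 (-2.14) and Cxcl1 (1.20). The 16 NF-kB targets had a median of 0.12 (camera adjusted p = 0.602), with Lcn2 at 2.50 and Saa3 at -1.28. Camera adjusted p was 0.408 both for 25 genes of hypoxia and glycolysis (median 0.12) and for 19 p53 targets (median 0.05), of which Gadd45a (1.25) rose adjusted over the list alone. Without control 1 the hypoxia and glycolysis list passed (median 0.33, camera adjusted p = 7.11e-04; range over all alternatives 7.11e-04 to 0.907), and with all tumours it had an adjusted p = 0.907 with an estimated correlation. The unfolded protein response had a median of 0.14 over 21 genes (camera adjusted p = 0.577), heat shock 0.09 over 13 (0.896), cytosolic ribosomal proteins 0.05 over 24 (0.961) and oxidative phosphorylation -0.0017 over 38 (0.577). Sterol synthesis lay at the threshold, with a median of -0.14 over 17 genes (camera adjusted p = 0.0516; range over all alternatives 1.41e-04 to 0.863), among them Hmgcs1 at -0.35 and Idi1 at -0.48. It passed with the stricter filter, both other choices of probe set, median centring, the second quantile normalisation, array weights, the block and the muscle covariate, and without control 1 (-0.28) or Bptf KD 3 (-0.16), but had an adjusted p = 0.863 with an estimated correlation. Its median was 0.02 without control 3.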

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

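The tests of the share of non-tumour cells, fat pad tissue, muscle and skin, muscle tissue, dilution and macrophages, and the comparison of Bptf by probe set, were chosen only after the result was seen. A signal appeared in data that the comparisons by gene leave out: of 1248 probe sets without a single gene name, 10 passed the threshold in limma, 5 higher and 5 lower in Bptf KD tumours.

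Adipocyte and matrix genes were lower in Bptf KD tumours as lists by camera with the preset correlation and by fry. With an estimated correlation neither list passed (camera adjusted p = 0.182 for each). A lower share of all non-tumour cells alike is argued against. The macrophage list had a median of 0.26 (95% bootstrap interval 0.08 to 0.39) and the fibroblast list of -0.77 (-0.97 to -0.70). Bootstrap intervals in this section resample the genes of a list, not the tumours. By tumour the macrophage list mean was 11.4 to 11.7 in controls and 11.4 to 11.8 in Bptf KD tumours. That list did not pass (camera adjusted p = 0.375), and its members Cd163 (-2.13), Cd209a (-1.20) and Mrc1 (-0.75) fell, while 19 of 23 were positive. A lower share of some non-tumour cells stays open. Muscle and skin in the tumour labelled control 2 are argued against too: without it the adipocyte median kept 0.931 of its size (0.80 to 0.950) and the fibroblast median 1.15 (0.924 to 1.30). More fat pad tissue taken with the controls cannot be told apart from an effect of Bptf KD, because the gap between the groups in the adipocyte list mean (1.65, against a range of 0.713 among controls) follows the groups either way. A change in the stroma brought by Bptf KD also stays open, untested.

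The tumour labelled control 2 stood apart and had low Bptf. Muscle tissue in the piece may account for part of how it stood apart, as 18 of 18 muscle genes were at least 2-fold above controls 1 and 3. RNA degradation may too, with the highest 3-prime minus 5-prime difference for Tfrc (1.54, others 1.34 to 1.5) and Pcx (0.72, others -0.29 to 0.44). These differences cannot decide it, because Tfrc barely exceeded the next tumour and Pcx was higher in every control than in every Bptf KD tumour. Among the controls Pcx also followed the order of the adipocyte list means (10.09, 9.66 and 9.38 in controls 2, 1 and 3). The low Bptf of control 2 on the probe set used (-0.87) may in part reflect RNA loss from long transcripts, whose median was -0.76 over 33 genes (middle 95% of 10000 random lists -0.265 to 0.205). The falls of -2.58 and -2.74 on 2 other Bptf probe sets, however, were reached by only 1 and 0 of 55 probe sets of long transcripts, so that this loss is not shown to account for them. Dilution by tissue without dividing cells, as the whole of the lower Bptf, is argued against by the cell cycle list. That list was taken after a first test on the epithelial list (0.09) was set aside because skin carries its genes. In control 2 the cell cycle list was at -0.24 (interval -0.48 to -0.07), with 0.408 between controls 1 and 3 in the list mean. It cannot decide on dilution by tissue with dividing cells, which skin may hold. A smaller dilution stays open too, and the hypoxia list was at -0.62. A Bptf KD tumour under a control label cannot be told apart from RNA loss: control 2 lay nearer to the Bptf KD mean at 44.4% of the 412 genes called without it, 110 of 179 higher and 73 of 233 lower genes, while its adipocyte list mean of 10.09 went with the controls (Bptf KD 6.95 to 7.72), as did its fibroblast list mean of 11.0 (10.1 to 10.3). Loss from long transcripts also cannot be told apart from knockdown as a part of the lower Bptf of the KD tumours against controls 1 and 3, with a long-transcript median of -0.39 (-0.55 to -0.23) beside -0.92 for Bptf. Of the 33 genes, 3 fell at least that far. The other 3 Bptf probe sets were also lower in the KD tumours than in controls 1 and 3. They lay at 8.37 to 9.15 against 10.30 and 10.04, at 6.37 to 6.53 against 8.27 and 8.02, and at 7.27 to 7.37 against 7.82 and 7.81. For the KD tumours these probe sets were not set beside those of other long transcripts.

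The interferon and MHC class I lists were higher in Bptf KD tumours by camera with the preset correlation only (adjusted p = 0.427 for each with an estimated correlation), limma called 0 of their genes (10 and 6 higher at an unadjusted p under 0.05), and MHC class I did not pass without control 2 (0.0519; range over all alternatives 1.38e-04 to 0.427). Less dilution by fat pad RNA would raise genes of the other cells alike. As the only change it is argued against by the cell cycle median of -0.46 (-0.53 to -0.40). The proteasome median was 0.02 (-0.03 to 0.08) but cannot decide, as fat pad cells may hold these genes too. Less dilution as a part stays open, since Bptf KD may itself lower cell cycle genes and the epithelial list was higher (median 0.44). More macrophages cannot be told apart from a change within the tumour cells, because the intervals of the interferon list (0.38, 0.29 to 0.48) and the macrophage list (0.26, 0.08 to 0.39) overlap. An effect of Bptf KD on these genes stays open, untested.

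The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 75 genes and the highest other 0, so 1 split of 10 gave as many genes. For lists it called 8 and the highest other 12, and 7 splits gave as many. For the MHC class I list the camera p was 2.09e-04 and the smallest other 5.58e-05, and 2 splits gave as small a p.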

How the results depend on the processing

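The tests with the muscle list as a covariate were chosen only after the result was seen. With all tumours kept, and leaving aside the ordinary test and the fold threshold, which were run for the count of genes alone, 571 values of named genes and 253 of lists held their direction and side of the threshold, while 22 and 8 lost their call, 21 and 11 gained one and 10 and 11 reversed. Bptf and the MHC class I list are not in these counts, and the RNA quality differences of Actb and Gapdh are counted with the named genes. The gained gene calls came with array weights, and for Usp18 and Cldn3 with the replicate block. The cause of the changes below was not tested, except that fewer genes or tumours were used in some. The stricter filter gave 42 genes (5 higher, 37 lower), the probe set with the largest SD 9 higher and the second quantile normalisation 9 higher, the muscle covariate 50 genes (9 higher; 37 of the 75 shared), and the ordinary test 1 gene. Array weights, for which limma warned that its fit had not converged, gave 1676 genes (986 higher, 690 lower) and -0.88 for Bptf. The labels do not say whether replicate numbers pair the tumours. Correlations of deviations from the group means cannot settle it, since the tumour labelled control 2 enters the control mean. They were 0.0054, 0.279 and 0.372 for same numbers and ran from -0.445 to 0.353 for different numbers. The replicate block gave 107 genes, 92 of them lower, with 60 of the 75 shared. With an estimated correlation 0 lists passed in camera (3 at an unadjusted p under 0.05), and MHC class I stayed at 0.32 (adjusted p = 0.427 with an estimated correlation). Signs reversed with the mean of all probe sets (proteasome -0.01, NURF list 0.021, p53 -0.0025, Baz1b 0.086), the largest SD (NURF list 0.02, endothelial -0.037, Baz1b 0.043) and median centring (Rbbp4 -0.0067). They reversed with array weights for immune ligands (-0.048), oxidative phosphorylation (0.026), muscle (0.88), Rbbp4 (-0.026), Tapbp (-0.086), Pvalb (0.11), Casq1 (0.26) and Tcap (0.12), and with the muscle covariate for immune ligands (-0.016), oxidative phosphorylation (0.028), Rbbp4 (-0.012), Tapbp (-0.0011) and muscle (0.0050, near 0 by construction, since the covariate is that list's mean). Leaving out each tumour in turn gave 0 to 412 genes, 0 to 179 higher and 0 to 233 lower, 7 to 11 lists, -0.92 to -0.46 for Bptf and 0.25 to 0.41 for MHC class I. Lists that changed sign ran from -0.15 to 0.072 for MHC class II, -0.005 to 0.078 for proteasome, -0.065 to 0.03 for NURF, -0.076 to 0.17 for immune ligands, -0.04 to 0.33 for hypoxia, -0.066 to 0.071 for oxidative phosphorylation, -0.51 to 0.063 for squamous, -0.063 to 0.105 for endothelial, -2.14 to 0.02 for muscle and -0.285 to 0.02 for sterol synthesis. Genes that did so ran from -0.17 to 0.057 for Baz1b, -0.04 to 0.03 for Rbbp4, -0.047 to 0.26 for Baz2a, -0.22 to 0.58 for Tapbp and -0.14 to 0.058 for Smarca5. The RNA quality differences ran from -0.09 to 0.145 for Actb and -0.013 to 0.057 for Gapdh. The red blood cell list has a value only without the dim filter. Of the named genes, signal limits Cidec, Rerg, Marveld3, Tek, Acox2 and Dsc2, each with a group mean below the dim level of 6.09.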

Other observations

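No tests in this part were chosen only after the result was seen, but the genes Lbp, Lrg1, C1s1, Serping1 and C2 were. Of genes past the threshold that belong to no list, Serpina3n fell 6.98-fold, from 10.01 ± 0.24 to 7.21 ± 0.18 (SD, n = 3 each; limma adjusted p = 0.00364). The lipopolysaccharide-binding protein gene Lbp fell 4.19-fold, Lrg1 4.08-fold, the complement protease gene C1s1 5.45-fold, the complement inhibitor gene Serping1 3.78-fold and C2 2.62-fold.

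Within lists that did not pass as a whole, members went both ways. Among macrophage markers Cd209a (-1.20), Cd163 (-2.13) and the mannose receptor gene Mrc1 (-0.75) fell adjusted over the list alone, while 19 of the 23 were positive, among them Aif1 (0.40), and fry's mixed test gave an adjusted p of 7.32e-04. Of the endothelial markers, Tek (-1.30), Vwf (-0.98) and Plvap (-0.76) fell and Cldn5 (0.76) rose adjusted over the list alone (fry mixed adjusted p = 7.32e-04). The chemokine list had a fry mixed adjusted p of 0.00126. Without the tumour labelled control 2 the neutrophil genes S100a8 (1.29) and S100a9 (1.14) passed, as did Clec4e, over all genes in limma. With all tumours the differences were 0.78, 0.67 and 1.25, and none passed (limma adjusted p = 0.541, 0.571 and 0.181). The tumour labelled control 2 had the highest control level of each (10.96, 10.97 and 8.18), so leaving it out favours a smaller p. For S100a8 and S100a9 that level lay within the range of the Bptf KD tumours.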
